A study of Mus musculus with 157 samples.

How the data were processed

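The series holds 157 samples of cultured mouse bone marrow macrophages, 117 labelled RNA and 40 labelled genomic DNA. RNA was selected by poly-A and made into strand-specific libraries by the dUTP method, per the labels' protocols. Reads were aligned to mm10 with STAR and quantified with HOMER, per the labels' protocols, which give no versions. The 8 deposited expression tables give 1 value per gene symbol for 24940 genes, on the RefSeq transcript whose accession, position and length stand beside it. Their headers name no unit. The deposited values are in TPM (length-scaled transcript counts per fixed library total) as far as the values show: each value times its transcript length is a whole multiple of 1 step per library, and the kept transcripts sum to 528079 to 569594, so that the authors scaled the total to 1 fixed sum over all annotated transcripts before 1 transcript per gene was kept. Which of a symbol's transcripts was kept, and how reads shared by similar or overlapping genes were divided, is not stated, so genes with near copies are uncertain.

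Reads per gene were recovered by dividing each value times length by that step, with a tolerance of 0.15 read around whole numbers, within which at least 99.973% of values lay. The totals, 2.12 to 22.1 M reads per library with a median of 10.1 M, cover only the kept transcripts. On simulated tables of 3 depths all reads were recovered. Of 95 pairs of libraries within groups none were copies of each other (lowest chi-square per degree of freedom 2.54).

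Libraries were grouped by title, and columns were joined to samples by names. In 12 samples titled Tfe3WT the genotype field says Tfe3KO, and in replicate 3 of TfebWT MSUc the treatment field says PBS. Both followed the title, the second also being run as labelled. The particle table has columns for silica 1 to 3 and alum 1 and 2 where the labels list 2 silica and 3 alum samples, so silica 1 and 2 and alum 1 and 2 were used. Silica 3 and the first column of SGC0946 in PBS, for which the labels hold no sample, were not used here, which left 115 libraries. Times of exposure outside the time course and the dose of metformin are not given in the labels. Ampka1KO macrophages and their WT were grown in RPMI with 5 ng/mL M-CSF and the others in DMEM with 16 ng/mL, per the labels' protocols.

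The test planned was for counts. Since the tables hold TPM, the fallback fixed with it was used: limma 3.58.1 (R 4.3.3, trend, no robust option) on log2(TPM + 1), with all groups of an experiment in 1 fit and a gene tested if it reached 1 TPM in as many libraries as the smallest group holds. Calls are at a Benjamini-Hochberg adjusted p under 0.05, all two-sided. The 40 contrasts compare a particle with PBS, a genotype or drug with its control, and, as an interaction, the particle response between them. Of 29 gene lists fixed before the data were examined 27 had at least 2 genes tested in a contrast, and fry of limma tested whether each moved on balance in 1 direction, adjusted over 1015 tests of lists and contrasts. fry called 468 of these, and 688 for change in either direction. The text names the gene targeted in each experiment, up to 10 of the largest rises and falls with an absolute log2 change of at least 1, a mean of at least 5 TPM (planned as CPM) and no overlap between groups (not required of interactions), the 3 genes of smallest p where none passed, the 4 members of each list with the smallest p, list members so named elsewhere in the experiment, and the 5 regions per list with the largest authors' change. Short RNA genes and overlapping pairs that met the rule rest on few or shared reads and are not named, and some other genes that met it are not reported here. Chosen after their values were seen are the genes listed as shared by all 8 experiments, 0610040F04Rik, the marker genes given for Ampka1KO, Ifi202b, and Xist and Ddx3y.

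For DOT1L, TFE3 and TFEB the deposited lists of peaks gained or reduced with MSUc were annotated with the distance to the nearest start site by HOMER, per the file headers, and every peak lies more than 3 kb from one. How peaks were called is not stated. For H3K27ac and H3K4me3 the authors counted tags in windows around accessible regions and scaled this signal to 1 library total with HOMER, per the file headers. The authors then listed regions by a log2 change, with a p-value and an adjusted p-value of their own test. Some of the columns of signal belong to 4 libraries that the labels do not list as used here, and no test was made on the signal, since only selected regions are listed. Overlap of at least 1 bp was counted with bedtools 2.31.1, and the authors' nearest gene was set against the 5 hour calls by Fisher's exact test. Genome-wide tracks were not analysed here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

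Data were simulated for 5 hours at the real means and depths, with 200 changed genes of 12031 and 2 libraries a side. limma found 66% of genes changed by 1 log2 unit and 99% of those changed by 2. Of calls 4.6% were false (2.1 to 6.9% in other contrasts). Pseudocounts, filter, threshold, replicate block, groups alone, regrouping and leaving out each library were planned as alternatives. Median-of-ratios scaling, voom on recovered reads, crossed numbers, the removal of all Tfe3KO libraries numbered 1, and the refits behind the regions were added after the data were seen. Of 31 contrasts whose groups share replicate numbers, every pair of 3 correlated at over 0.1 in 1, CPPD against PBS in Tfe3WT (r = 0.12 to 0.19 across genes), from the data and not the labels. With 2 pairs, too few to show pairing by this rule, r was 0.48 after 10 minutes and 0.12 and 0.14 for Bhlhe40KO in PBS and MSUc, and in 4 of the time course the numbers ran crossed.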

Results

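RNA sequencing of mouse bone marrow-derived macrophages exposed to particles was read from 8 tables, each 1 experiment. They hold a time course of monosodium urate crystals (MSUc), a comparison of 4 particles, 3 experiments with a gene deleted or transgenic (Tfe3, Tfeb, Prkaa1, which encodes the AMPK catalytic subunit alpha 1), 1 with Bhlhe40 or Bhlhe41 deleted, and 2 with a drug (the DOT1L inhibitor SGC0946, or metformin). Particles were given at 250 ug/mL and controls received PBS. Groups held 2 or 3 libraries, 115 in all, of 2.12 to 22.1 M reads (median 10.1 M). Lists of regions gained or reduced with MSUc in chromatin immunoprecipitation (ChIP-seq) for DOT1L, TFE3, TFEB, H3K27ac and H3K4me3 were also used.

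Levels are means ± SD in TPM, a count of transcripts scaled for transcript length and library total, and changes are log2 ratios ± SE from limma, with libraries as replicates. A gene rose or fell where its adjusted p was under 0.05 in limma. For each gene list fixed before the data were examined, the counts are of members that rose or fell, then the counts adjusted over the list alone where these differ, then the adjusted p of fry. This tests whether the genes of a list moved on balance 1 way and compares the list with no other genes. Coordinates are mm10.

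The time course asked how soon the response to MSUc begins, with 2 PBS and 2 MSUc libraries at each time. After 10 minutes Egr1, an immediate early zinc finger factor, had risen by 3.51 ± 0.32 (48.6 ± 15.6 against 3.29 ± 0.962 TPM). Zfp36, whose product destabilises cytokine mRNAs, had risen by 1.16 ± 0.11 (487 ± 16.1 against 218 ± 11.9 TPM). After 30 minutes Egr3 was up by 4.55 ± 0.26 (42.4 ± 0.0778 against 0.867 ± 0.317 TPM) and the orphan nuclear receptor gene Nr4a1 by 3.96 ± 0.27. Osm, which encodes the cytokine oncostatin M, was up by 3.34 ± 0.27 (80.3 ± 13.8 against 6.97 ± 0.479 TPM). Among immediate early genes 23 rose and 0 fell of 30 tested (25 and 0 adjusted over the list alone, fry adjusted p = 1.9e-07). Among inflammatory genes 10 rose and 0 fell of 24 tested (12 and 1 adjusted over the list alone, fry adjusted p = 5.8e-06). Tnf was up by 2.35 ± 0.24 and the chemokine gene Ccl4 by 2.96 ± 0.22. After 1 hour Cxcl2, a neutrophil chemokine, had risen by 6.02 ± 0.62 (608 ± 116 against 8.81 ± 4.45 TPM) and Tnfaip3, a brake on NF-kappaB, by 2.70 ± 0.15. Dot1l, the H3K79 methyltransferase, rose by 0.94 ± 0.12 (68.8 ± 10.4 against 35.1 ± 0.544 TPM) and Bhlhe40, a bHLH repressor, by 1.25 ± 0.20. Bmf, a pro-apoptotic BCL2 family gene, fell by 1.45 ± 0.12 (7.25 ± 0.92 against 21.5 ± 2.63 TPM).

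limma called 7 of 12350 genes, 6 up and 1 down after 10 minutes. It called 84 genes, 84 up and 0 down after 30 minutes. After 1 hour it called 405, 288 up and 117 down (351 up and 78 down after median-of-ratios scaling). With a block of crossed replicate numbers, read from the data, counts were higher (below). In a fit of the compared groups alone limma called 0, 0 and 56 genes, with 248, 385 and 1270 at an unadjusted p under 0.05. Of the early changes named only those of Cxcl2 and Tnfaip3 at 1 hour passed that fit. The inflammatory list at 30 minutes did not (fry adjusted p = 0.053). Leaving out PBS replicate 1 or MSUc replicate 1 or 2 took the 10 minute count to 2, 3 or 3. The 30 minute count was 46 or 47 without PBS replicate 1 or MSUc replicate 2. The 1 hour count was 192, 250, 244 or 240 without PBS replicate 1 or 2 or MSUc replicate 1 or 2.

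After 2 hours Gdf15, a stress-induced cytokine gene, had risen by 4.18 ± 0.25 (256 ± 2.1 against 13.2 ± 0.226 TPM). The cystine transporter gene Slc7a11 had risen by 4.16 ± 0.28 and Ptgs2, the inducible cyclooxygenase, by 4.56 ± 0.28. Bmf had fallen by 3.29 ± 0.12 and Tifab, an inhibitor of TRAF6 signalling, by 2.90 ± 0.22 (2.25 ± 0.124 against 23.4 ± 4.63 TPM). Subunits of the lysosomal proton pump (V-ATPase) gave 9 and 0 of 17 (fry adjusted p = 1.7e-07) up and down. After 5 hours V-ATPase subunits gave 15 and 0 of 17 (fry adjusted p = 2.5e-09). Among them Atp6v1h rose by 2.17 ± 0.09 (233 ± 6.2 against 50.9 ± 1.49 TPM) and Atp6v1c1 by 1.54 ± 0.11. The wider list of lysosomal genes with CLEAR motifs, bound by TFEB and TFE3, moved in both directions at 5 hours, 6 and 12 of 41 (fry adjusted p = 0.33) up and down. The hydrolase gene Sgsh fell (11.3 ± 3.23 against 56.6 ± 7.25 TPM). The sign of the list's balance turned from down to up after median-of-ratios scaling (fry adjusted p = 0.59).

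At 5 hours Procr, the protein C receptor, stood at 289.7 ± 76.5 against 6.92 ± 0.848 TPM and Acod1, which makes itaconate, at 235 ± 2.49 against 8.71 ± 1.54 TPM. Inflammatory genes gave 20 and 0 of 24 (fry adjusted p = 7.8e-08) up and down. NRF2 targets, which counter oxidants, gave 13 and 0 of 20 (fry adjusted p = 0.0011), with the haem oxygenase gene Hmox1 at 3.25 ± 0.42. Genes of the integrated stress response gave 13 and 2 of 22 (fry adjusted p = 2.2e-07), with Chac1 at 3.71 ± 0.30. Those of glycolysis gave 17 and 1 of 23 (fry adjusted p = 5.3e-07), with the glucose transporter gene Slc2a1 at 176 ± 12.5 against 20.3 ± 2.29 TPM. Macrophage identity genes gave 1 and 11 of 21 (fry adjusted p = 2.8e-06), with Maf at 21.7 ± 0.776 against 156 ± 49.1 TPM. Mertk, an efferocytosis receptor, stood at 7.1 ± 2.1 against 35.6 ± 1.17 TPM and Irf8 changed by -1.23 ± 0.13. Dendritic cell markers moved the other way, 3 and 0 of 7 (fry adjusted p = 3.2e-05). The AMPK subunit genes gave 0 and 3 of 6 (fry adjusted p = 4.9e-05). In the fit of the compared groups alone, fry adjusted p was 0.12 for the NRF2 targets, 0.059 for the AMPK subunits and 0.054 for the dendritic cell markers. Dot1l reached 180.4 ± 15.2 against 34.7 ± 2.85 TPM. Bhlhe40 reached 291 ± 25.7 against 29.1 ± 6.38 TPM and Bhlhe41 131 ± 26.9 against 27.1 ± 1.34 TPM. Sesn1, a stress gene that restrains mTORC1, fell by 3.45 ± 0.36 (7.95 ± 1.66 against 97.8 ± 26.5 TPM). limma called 4133 of 12350 genes, 1379 up and 2754 down (2035 up and 1492 down after median-of-ratios scaling, which shifts the median of all genes by 0.15 log2) after 2 hours, or 1015 from the compared groups alone and 2701 without MSUc replicate 1. After 5 hours it called 6093 of 12350 genes, 2026 up and 4067 down (3078 up and 2533 down after median-of-ratios scaling, which shifts the median of all genes by 0.22 log2).

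**Figure D1:**
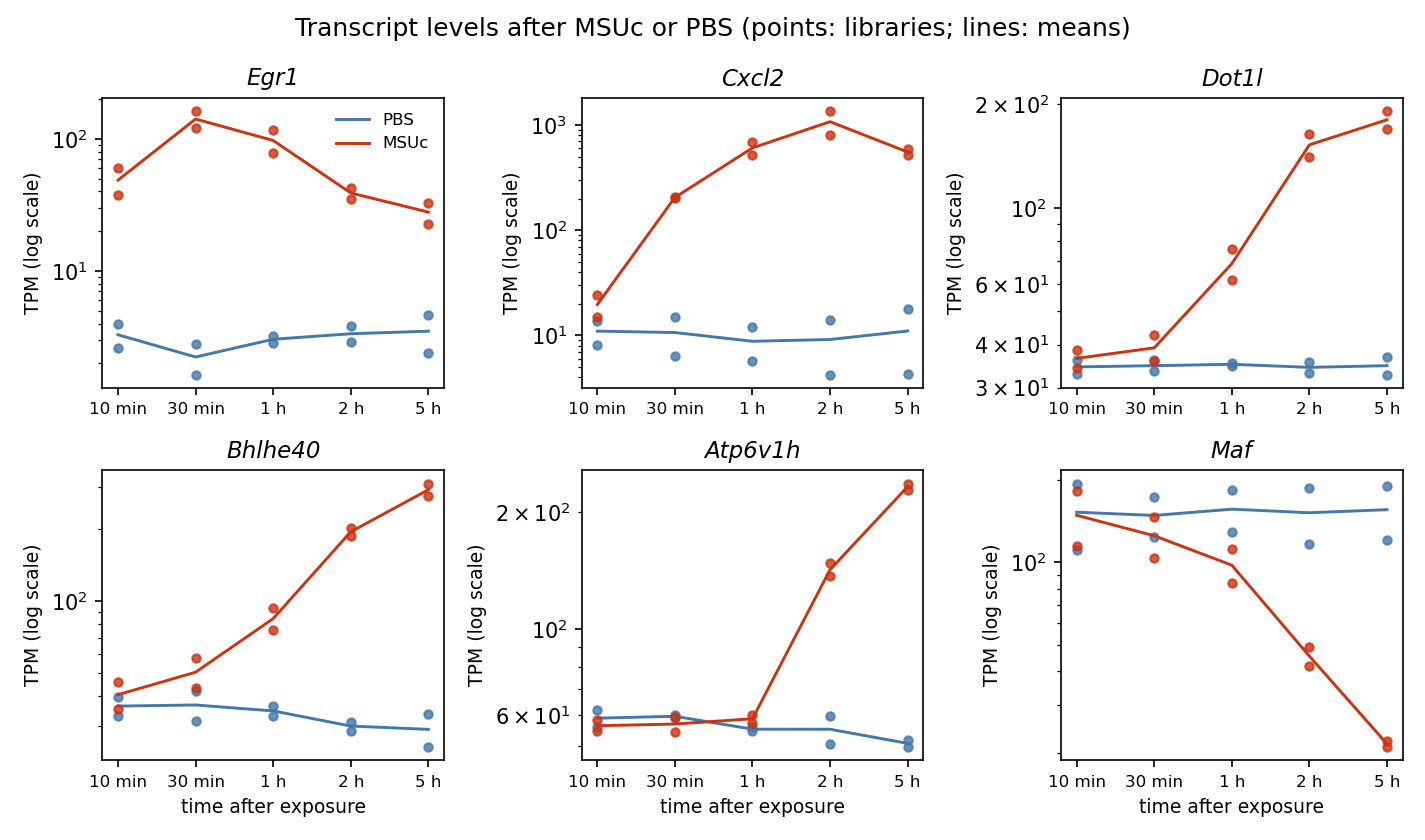
Mean level in TPM (log scale) of 6 genes against time after MSUc or PBS, with 1 point per library (2 per group and time). With MSUc both libraries lie above both PBS libraries for Egr1 at every time and at 5 hours for Dot1l (170 and 191 TPM against 32.7 and 36.8 TPM), Cxcl2, Bhlhe40 and Atp6v1h, and at 5 hours below them for Maf (21.1 and 22.2 TPM against 121 and 191 TPM).

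Against PBS, MSUc was tested in 8 experiments. Of 11186 genes tested in all of them 2738 passed in the same direction in each, 864 up and 1874 down (1433 and 831 after median-of-ratios scaling). Of the inflammatory list 16 of 30 genes rose in all 8, including Tnf, Nlrp3, Il1rn, Il10, Ccl3 and Cxcl2, and of the immediate early list 19 of 30. V-ATPase subunits made up 7 of 17, glycolysis genes 9 of 24, stress response genes 8 of 24 and NRF2 targets 6 of 20, among them Gclc, Hmox1 and Txnrd1. Dot1l, Aff4 and Ell, which act in H3K79 methylation and elongation, also rose in all 8, as did Bhlhe40. Macrophage identity genes fell, 9 of 21 in all 8, including the M-CSF receptor gene Csf1r, the complement genes C1qa, C1qb and C1qc, Irf8 and Maf. Of the dendritic cell markers 3 of 12 rose in all 8. Prkag1, Prkag2 and Stk11, an AMPK kinase, also fell in all 8. With TfebWT MSUc replicate 3 in PBS, as its treatment label states, 0 genes passed in all 8 by limma (1 in the Tfeb experiment). Without this library 2597 passed in all 8.

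The comparison of particles asked which parts of the response depend on the particle, with 3 PBS, 3 MSUc and 3 calcium pyrophosphate (CPPD) libraries and 2 each labelled silica and alum. Column and label numbers differ for silica and alum, and the silica column left over was not used. With CPPD Acod1 rose by 7.22 ± 0.30 (637 ± 165 against 3.22 ± 0.612 TPM). The acute phase gene Saa3 rose by 6.05 ± 0.54 and Clec4e, a receptor for damaged cells, by 5.31 ± 0.16. Interferon-stimulated genes gave 27 and 0 of 27 (fry adjusted p = 0.00074) up and down, with the GTPase gene Gbp2 at 4.10 ± 0.38. With MSUc they gave 11 and 0 of 27 (10 and 0 adjusted over the list alone, fry adjusted p = 0.2). The difference between these 2 particles was not tested. NRF2 targets gave 19 and 0 of 20 (19 and 1 adjusted over the list alone, fry adjusted p = 1.2e-07) with MSUc and 17 and 0 of 20 (fry adjusted p = 5e-07) with CPPD. With MSUc Txnrd1 rose by 3.71 ± 0.10 and the glutathione synthesis gene Gclc by 3.79 ± 0.11. V-ATPase subunits gave 13 and 0 of 17 (fry adjusted p = 2.4e-07) with MSUc and 12 and 0 of 17 (fry adjusted p = 2.3e-06) with CPPD.

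In the libraries labelled silica the chemokine genes Ccl7 (572 ± 210 against 2.24 ± 0.873 TPM) and Ccl3 (2496 ± 729 against 42.2 ± 2.17 TPM) and the fatty acid carrier gene Fabp4 (1165 ± 194 against 81.4 ± 13.8 TPM) rose. Inflammatory genes gave 27 and 0 of 28 (fry adjusted p = 5.8e-06) up and down. With them rose mast cell markers, 2 and 0 of 2 (fry adjusted p = 8.4e-05) (for alum 1 and 0 of 2 (fry adjusted p = 0.00011) and for MSUc 1 and 0 of 2 (fry adjusted p = 0.011)), and neutrophil markers, 6 and 1 of 8 (fry adjusted p = 0.012) (0.054 from the compared groups alone and 0.073 without silica replicate 2). V-ATPase subunits gave 11 and 2 of 17 (fry adjusted p = 3.8e-08). Lysosomal CLEAR genes gave 8 and 28 of 41 (fry adjusted p = 0.0016) (0.82 after median-of-ratios scaling and 0.08 from the compared groups alone). In the libraries labelled alum Gdf15 (103 ± 11.7 against 4.91 ± 1.75 TPM), Fosb (29.7 ± 8.64 against 0.732 ± 0.321 TPM) and Cxcl2 (73.3 ± 1.03 against 5.23 ± 1.59 TPM) rose. Genes of the DOT1L complexes gave 11 and 0 of 11 (fry adjusted p = 2e-05), with Dot1l at 118 ± 13.6 against 26.7 ± 0.713 TPM. Those of cholesterol synthesis gave 9 and 1 of 19 (fry adjusted p = 0.0056). Tpt1, a translation-associated gene, fell by 4.58 ± 0.88 (22.8 ± 0.253 against 571 ± 77.5 TPM) and the ribosomal protein gene Rplp2 by 2.93 ± 0.45. Both are short transcripts, which fell more than long ones in these libraries (Spearman rho = 0.55 between length and change across genes). Genes of the DOT1L complexes have long transcripts, so their rise runs with this trend too.

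limma called 7757 of 12314 genes, 2227 up and 5530 down (3502 up and 3377 down after median-of-ratios scaling, which shifts the median of all genes by 0.27 log2) with MSUc. It called 6454 of 12314 genes, 2044 up and 4410 down with CPPD. After this scaling 3057 rose and 2719 fell (median shift 0.20 log2). For libraries labelled silica it called 8417 of 12314 genes, 3007 up and 5410 down. After this scaling 4451 rose and 3832 fell (median shift 0.32 log2). For those labelled alum it called 5694 of 12314 genes, 3335 up and 2359 down (2735 up and 2819 down after this scaling). Across all 4 particles 737 genes rose and 985 fell. MSUc and CPPD shared 1486 rises and 3922 falls, against 370 and 1980 for independent lists, and 82 genes moved in opposite directions. Their fold changes correlated across 12314 genes with r = 0.84, against 0.50 for simulated unchanged groups that share the PBS libraries (covariance 0.525 against 0.026). The alum and silica labels shared 1305 rises and 1190 falls, against 814 and 1036, with 1554 genes opposite. Here r was 0.36 against 0.40 and the covariance 0.231 against 0.026. Genes are not independent replicates, and part of each excess may come from the shared PBS libraries, which are too few to split.

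The Tfe3 experiment asked whether loss of TFE3, a regulator of lysosomal genes, changes the response to 3 particles, with 3 libraries in each of 8 groups. In Tfe3WT libraries CPPD raised interferon-stimulated genes, 27 and 0 of 27 (fry adjusted p = 2e-06) up and down. Rsad2 rose by 4.45 ± 0.42 and Isg15 by 3.45 ± 0.27. With silica Ccl3 rose to 3599 ± 318 against 41.6 ± 5.48 TPM and Cxcl2 to 1214 ± 33.6 against 5.38 ± 0.697 TPM. Lysosomal CLEAR genes gave 9 and 27 of 41 (10 and 27 adjusted over the list alone, fry adjusted p = 1.3e-06) with silica and heat shock genes 9 and 1 of 11 (fry adjusted p = 6e-13). With MSUc V-ATPase subunits gave 16 and 0 of 17 (fry adjusted p = 1.1e-08) and Dot1l rose to 134 ± 8.48 against 35.7 ± 5.08 TPM. limma called 7883 of 12796 genes, 2564 up and 5319 down (3741 up and 3584 down after median-of-ratios scaling, which shifts the median of all genes by 0.19 log2) with MSUc. With CPPD it called 7703 of 12796 genes, 2361 up and 5342 down. After this scaling 3596 rose and 3291 fell (median shift 0.21 log2). With silica it called 8424 of 12796 genes, 3683 up and 4741 down.

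Tfe3 itself (NM_001271490, mm10 chromosome X, 7762661 to 7775202) was at 68.3 ± 1.66 against 98.4 ± 5.01 TPM in Tfe3KO against Tfe3WT libraries in PBS. Its log2 change in PBS was -0.52 ± 0.08 (adjusted p = 0.001, and 0.074 from the compared groups alone). With MSUc it was at 85.7 ± 1.36 against 82.1 ± 2.05 TPM (log2 0.06 ± 0.08, adjusted p = 0.73). The transcript was thus not lost. A genotype field gives Tfe3KO for both sets and the groups follow the titles, so directions below are for libraries labelled Tfe3KO by title. In PBS lysosomal CLEAR genes were lower, 1 and 9 of 41 (4 and 13 adjusted over the list alone, fry adjusted p = 0.0042) up and down, with fry adjusted p = 0.097 from the compared groups alone. The protease gene Tpp1 fell by 0.58 ± 0.05 and the glucosidase gene Gaa by 0.59 ± 0.08. With MSUc they gave 0 and 22 of 41 (0 and 24 adjusted over the list alone, fry adjusted p = 1e-07). The sialidase gene Neu1 fell by 1.12 ± 0.08, Gaa by 1.10 ± 0.08 and the channel gene Mcoln1 by 0.98 ± 0.07. V-ATPase subunits gave 1 and 10 of 17 (1 and 12 adjusted over the list alone, fry adjusted p = 1.6e-05) with Atp6v1d at -0.83 ± 0.08. The folliculin and Rag GTPase list gave 0 and 5 of 12 (1 and 5 adjusted over the list alone, fry adjusted p = 3.4e-07), with Rragd at 3.97 ± 0.451 against 16.9 ± 1.52 TPM and Flcn at -0.87 ± 0.07. Autophagy genes gave 0 and 7 of 22 (2 and 11 adjusted over the list alone, fry adjusted p = 5.1e-06). Slc25a44, a mitochondrial amino acid carrier gene, fell by 1.59 ± 0.07 (16.8 ± 1.11 against 52.3 ± 1.39 TPM), the glycolytic gene Hk2 by 0.67 ± 0.11 and Fabp4 by 0.94 ± 0.13. Il10, an anti-inflammatory cytokine gene, rose by 1.26 ± 0.25 (32.8 ± 11.5 against 12.8 ± 2.32 TPM).

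**Figure D2:**
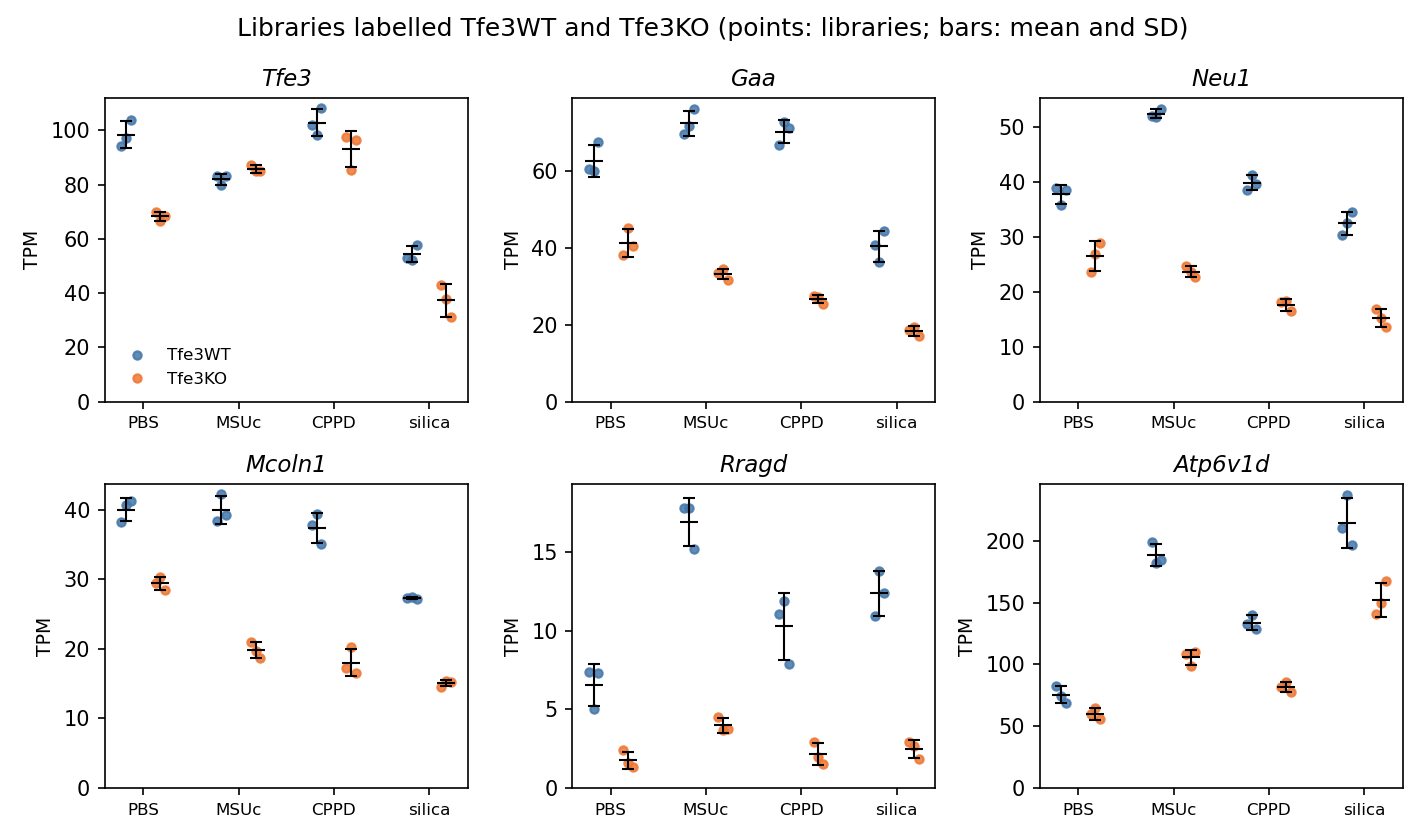
Level in TPM of 6 genes in PBS and with MSUc, CPPD or silica, with 1 point per library and bars for the mean and SD of 3 libraries labelled Tfe3WT (blue) or Tfe3KO (orange). Gaa, Neu1, Mcoln1 and Rragd lie lower in each Tfe3KO library than in each Tfe3WT library of the same treatment, as for Neu1 with MSUc (22.7 to 24.7 TPM against 51.8 to 53.3 TPM), whereas Tfe3 does not with MSUc or CPPD.

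limma called 303 of 12796 genes, 126 up and 177 down (132 up and 127 down after median-of-ratios scaling) between the genotypes in PBS and 1372 of 12796 genes, 524 up and 848 down with MSUc. From the compared groups alone 0 genes passed in PBS by limma (1222 at an unadjusted p under 0.05) and 767 with MSUc. Leaving out Tfe3WT PBS replicate 1 or Tfe3KO PBS replicate 1, 2 or 3 gave 178, 487, 178 or 143 genes in PBS. Leaving out all 4 Tfe3KO libraries numbered 1, which carry Xist where the others carry Ddx3y, gave 463.

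The response to each particle was compared between the genotypes by an interaction term. Slc25a44 went from 13.8 ± 1.05 to 16.8 ± 1.11 TPM with MSUc in Tfe3KO and from 14.7 ± 0.741 to 52.3 ± 1.39 TPM in Tfe3WT libraries. The responses differed by -1.50 ± 0.10. Slc26a11, a lysosomal sulfate transporter gene, differed by -1.56 ± 0.16 with MSUc, -1.26 ± 0.16 with CPPD and -1.36 ± 0.16 with silica. The metallopeptidase gene Amz1 differed by -1.66 ± 0.21, -1.48 ± 0.21 and -1.32 ± 0.21. The change of the lysosomal list lay lower in Tfe3KO than in Tfe3WT, 0 and 6 of 41 (0 and 11 adjusted over the list alone, fry adjusted p = 0.00029) up and down with MSUc. With CPPD it gave 0 and 7 of 41 (0 and 12 adjusted over the list alone, fry adjusted p = 0.00011) and with silica, which lowered the list in Tfe3WT, 0 and 7 of 41 (0 and 11 adjusted over the list alone, fry adjusted p = 0.00043). limma called 221 of 12796 genes, 53 up and 168 down for MSUc. It called 119 of 12796 genes, 43 up and 76 down for CPPD and 194 of 12796 genes, 59 up and 135 down (99 up and 68 down after median-of-ratios scaling) for silica. From the compared groups alone 78, 37 and 9 passed, Amz1 with silica not among them (adjusted p = 0.054). Leaving out Tfe3KO PBS replicate 1, 2 or 3 gave 422, 130 or 133 genes for MSUc, 327, 70 or 70 for CPPD and 729, 60 or 52 for silica. Leaving out Tfe3WT replicate 1 or 2 or Tfe3KO replicate 2 of the particle groups gave 135, 131 or 128 for MSUc and 70, 67 or 78 for CPPD. For silica, leaving out Tfe3WT PBS replicate 2, Tfe3WT silica replicate 1 or Tfe3KO silica replicate 2 or 3 gave 81, 61, 120 or 69, and leaving out all 4 Tfe3KO libraries numbered 1 gave 637.

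The Tfeb experiment asked the converse with a Tfeb transgene, in 2 TfebWT PBS libraries and 3 in each other group. Tfeb (NM_011549, mm10 chromosome 17, 47785744 to 47792416) was at 80.5 ± 5.72 against 44.1 ± 0.53 TPM in TfebTg against TfebWT libraries in PBS (adjusted p = 0.02). It was at 247 ± 49.3 against 28.4 ± 2.65 TPM with MSUc (log2 3.06 ± 0.13, adjusted p = 6.1e-07). With MSUc Hk2 rose by 1.81 ± 0.10 (115 ± 8.09 against 32.1 ± 3.11 TPM). Gne, an enzyme of sialic acid synthesis, rose by 2.33 ± 0.16 and the lipase gene Mgll by 1.87 ± 0.14. NRF2 targets were lower, 1 and 9 of 20 (2 and 12 adjusted over the list alone, fry adjusted p = 2.5e-06) up and down, with Gclc at -0.88 ± 0.10. Immediate early genes gave 0 and 11 of 30 (0 and 17 adjusted over the list alone, fry adjusted p = 0.00057), with Nr4a1 at -1.36 ± 0.17. The lysosomal list gave 2 and 1 of 41 (3 and 1 adjusted over the list alone, fry adjusted p = 0.94), its balance turning from up to down after median-of-ratios scaling (fry adjusted p = 0.95). Stromal markers, at low levels, moved too, 0 and 4 of 6 (0 and 5 adjusted over the list alone, fry adjusted p = 0.00022), with Col1a1 at 2.59 ± 0.512 against 7.63 ± 2.08 TPM. So did macrophage identity genes, 0 and 3 of 20 (1 and 10 adjusted over the list alone, fry adjusted p = 0.0023). In PBS the macrophage identity list was lower, 0 and 4 of 20 (0 and 10 adjusted over the list alone, fry adjusted p = 0.00036), with C1qa at -1.07 ± 0.09. Stromal markers were lower in PBS as well, 0 and 0 of 6 (0 and 4 adjusted over the list alone, fry adjusted p = 0.0041), as were those of dendritic cells, 0 and 0 of 8 (0 and 3 adjusted over the list alone, fry adjusted p = 0.024). The latter had fry adjusted p = 0.15 from the compared groups alone, 0.072 with a pseudocount of 0.1 and 0.28 with no filter, and 0.14, 0.074 and 0.056 without TfebWT PBS replicate 2 or TfebTg PBS replicate 2 or 3. With MSUc they gave 0 and 0 of 8 (0 and 2 adjusted over the list alone, fry adjusted p = 0.029), or 0.12 with that pseudocount, 0.058 with no filter and 0.062 with voom, and 0.075, 0.086, 0.052, 0.059 and 0.072 without TfebWT MSUc replicate 1, 2 or 3 or TfebTg MSUc replicate 1 or 3. The interaction was largest for Tfeb at 2.21 ± 0.19 and Hk2 at 1.97 ± 0.16.

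limma called 5455 of 11991 genes, 1507 up and 3948 down (2412 up and 1975 down after median-of-ratios scaling, which shifts the median of all genes by 0.26 log2) for MSUc in TfebWT. Between genotypes it called 86 of 11991 genes, 55 up and 31 down in PBS and 417 of 11991 genes, 245 up and 172 down with MSUc. For the interaction it called 12 of 11991 genes, 9 up and 3 down. With voom on recovered reads these 3 counts were 243, 654 and 41. One treatment field gives PBS for TfebWT MSUc replicate 3, and grouping it so left 1, 8, 36 and 3 genes. Under that grouping 5 of the changes named kept the call, among them those of Hk2, Gne, Mgll and Tfeb with MSUc, and 6 lost it. The lists were not tested under it. Tfeb in PBS no longer passed without TfebWT PBS replicate 1 or 2 or TfebTg PBS replicate 1 or 2 (adjusted p = 0.16, 0.18, 0.087 and 0.072). Leaving out TfebWT PBS replicate 1 or 2 or TfebTg PBS replicate 1 or 2 gave 35, 30, 54 or 46 genes in PBS. Leaving out TfebWT MSUc replicate 1, 2 or 3 or TfebTg MSUc replicate 3 gave 247, 257, 214 or 265 with MSUc. The interaction count became 5 or 4 without TfebWT PBS replicate 1 or 2, and 5 or 6 without TfebWT MSUc replicate 1 or 3. It became 6, 6 or 7 without TfebTg PBS replicate 1, 2 or 3, and 6 with the replicate block.

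Bhlhe40 and Bhlhe41 encode related bHLH repressors that MSUc raises, and the question was what their loss does, in 2 libraries per group. Bhlhe40 (NM_011498, mm10 chromosome 6, 108660629 to 108666925) was at 6.26 ± 0.946 against 67 ± 13 TPM in Bhlhe40KO against WT libraries in PBS (adjusted p 0.089 from the compared groups alone). It was at 13.9 ± 4.57 against 300 ± 18.9 TPM with MSUc (log2 -4.37 ± 0.19). limma called 10 of 12142 genes, 6 up and 4 down in PBS and 2 of 12142 genes, 0 up and 2 down with MSUc, where the other was 0610040F04Rik at -3.88 ± 0.23. It called 1 of 12142 genes, 0 up and 1 down for the interaction. Bhlhe41 (NM_001271768, mm10 chromosome 6, 145858243 to 145865420) was at 48 ± 2.47 against 52.8 ± 4.32 TPM in Bhlhe41KO against WT libraries in PBS (adjusted p = 0.49). It was at 49.9 ± 0.529 against 92.5 ± 3.42 TPM with MSUc (adjusted p = 0.0063), so its transcript does not show the deletion in PBS. In the libraries labelled Bhlhe41KO in PBS Ccl7 was at 22.9 ± 5.32 against 0.977 ± 0.274 TPM and the platelet factor gene Pf4 at 85.3 ± 7.7 against 17.3 ± 5.67 TPM. With MSUc neutrophil markers were higher, 3 and 0 of 12 (10 and 0 adjusted over the list alone, fry adjusted p = 0.0038) up and down. For Bhlhe41KO limma called 335 of 12142 genes, 214 up and 121 down (143 up and 124 down after median-of-ratios scaling) in PBS and 161 of 12142 genes, 103 up and 58 down (89 up and 78 down after median-of-ratios scaling) with MSUc. For the interaction it called 16 of 12142 genes, 1 up and 15 down. From the compared groups alone limma called 0 genes for either knockout in PBS or with MSUc, with 683, 526, 2022 and 1678 at an unadjusted p under 0.05. With voom on recovered reads Bhlhe41KO gave 714 genes in PBS, 354 with MSUc and 64 for the interaction.

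Single libraries moved these counts. For Bhlhe40KO in PBS leaving out WT replicate 1 or 2 or knockout replicate 1 or 2 gave 5, 4, 3 or 1 genes. With MSUc leaving out WT replicate 2 or knockout replicate 1 gave 4 and 4. The interaction count was 0 by limma without WT PBS replicate 1 or 2 or knockout PBS replicate 1 or 2 (637, 769, 552 and 558 at an unadjusted p under 0.05), and was 4, 3 or 2 without WT MSUc replicate 1 or 2 or knockout MSUc replicate 1. For Bhlhe41KO in PBS leaving out WT replicate 1 or 2 or knockout replicate 1 or 2 gave 59, 114, 112 or 41 genes. With MSUc leaving out WT replicate 1 or knockout replicate 1 or 2 gave 23, 23 or 6, and without the last the adjusted p of Bhlhe41 was 0.054. The interaction count was 4 or 9 without WT PBS replicate 1 or 2, 5 or 8 without WT MSUc replicate 1 or 2, 2 without knockout PBS replicate 2, and 1 and 1 without knockout MSUc replicate 1 or 2. Both Bhlhe41KO groups carry Ddx3y with Xist at 0.503 TPM or less, whereas WT replicate 1 carries Xist, so sex differs between these groups.

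The Ampka1 experiment asked what loss of AMPK alpha 1 does to the response, with 3 libraries per group grown in another medium and with less M-CSF (5 against 16 ng/mL). Prkaa1 (NM_001013367, mm10 chromosome 15, 5143861 to 5181899) was at 26 ± 1.56 against 24.5 ± 1.21 TPM in Ampka1KO against Ampka1WT libraries in PBS. It was at 28.8 ± 2.26 against 22 ± 1.15 TPM with MSUc (log2 0.37 ± 0.08, adjusted p = 0.0017). After median-of-ratios scaling its log2 changes were -0.11 in PBS and -0.13 with MSUc (limma adjusted p = 0.31 and 0.21). Its level thus does not show the deletion, and the groups are those labelled Ampka1KO. In PBS Lox, a collagen cross-linking enzyme gene, was higher (386 ± 57.6 against 13.7 ± 4.36 TPM). The lipoprotein gene Apoe was lower (680.3 ± 354 against 9808 ± 1020 TPM). Stromal markers gave 9 and 0 of 9 (fry adjusted p = 5.2e-05) up and down, with the matrix gene Sparc at 876 ± 114 against 53.5 ± 16 TPM. Cholesterol synthesis genes gave 1 and 10 of 20 (fry adjusted p = 0.00012). With MSUc stromal markers gave 9 and 0 of 9 (fry adjusted p = 1.2e-05). Lysosomal CLEAR genes gave 1 and 33 of 41 (fry adjusted p = 8.3e-07) and V-ATPase subunits 1 and 16 of 17 (fry adjusted p = 3.7e-06). Macrophage identity genes gave 0 and 18 of 21 (fry adjusted p = 1.2e-07), with the lipid receptor gene Trem2 at 98.7 ± 12.6 against 518 ± 12.4 TPM. Stromal transcripts moved with each of these groups. So did neutrophil markers, 7 and 0 of 11 (8 and 0 adjusted over the list alone, fry adjusted p = 0.0026) in PBS and 7 and 1 of 11 (fry adjusted p = 0.0031) with MSUc. Mast cell markers gave 2 and 0 of 2 (fry adjusted p = 6e-05) and dendritic cell markers 0 and 7 of 8 (1 and 7 adjusted over the list alone, fry adjusted p = 8e-05) with MSUc. By the interaction Cxcl2 went from 61.3 ± 38.5 to 234 ± 24 TPM with MSUc in Ampka1KO and from 2.88 ± 0.836 to 882 ± 111 TPM in Ampka1WT. The responses of Cxcl2 differed by -5.75 ± 0.48, those of Ccl3 by -4.76 ± 0.81 and those of Acod1 by -4.39 ± 0.58. The response of inflammatory genes was smaller, 1 and 19 of 25 (fry adjusted p = 1e-04), as was that of immediate early genes, 1 and 25 of 30 (fry adjusted p = 9e-05). That of V-ATPase subunits gave 0 and 15 of 17 (fry adjusted p = 3.4e-05), and cholesterol synthesis genes gave 14 and 1 of 20 (15 and 1 adjusted over the list alone, fry adjusted p = 3.2e-06). In PBS inflammatory and immediate early genes were already higher in Ampka1KO, 15 and 4 of 25 (fry adjusted p = 1e-04) and 17 and 3 of 30 (18 and 3 adjusted over the list alone, fry adjusted p = 6e-04). The response of dendritic cell markers was lower, 0 and 3 of 8 (fry adjusted p = 0.0051) (0.24 with voom on recovered reads). That of macrophage identity genes was lower too, 0 and 19 of 21 (fry adjusted p = 1.2e-06). In Ampka1KO Lyz2 went from 20900 ± 1400 to 7310 ± 1110 TPM with MSUc and Acta2 from 1010 ± 135 to 2410 ± 116 TPM. A falling share of macrophages with MSUc thus cannot be told apart from smaller responses within them. For MSUc in Ampka1WT limma called 8169 of 12834 genes, 2534 up and 5635 down (3903 up and 3624 down after median-of-ratios scaling, which shifts the median of all genes by 0.28 log2). Between genotypes in PBS it called 6117 of 12834 genes, 4342 up and 1775 down (3078 up and 3035 down after median-of-ratios scaling, which shifts the median of all genes by -0.18 log2). With MSUc it called 9212 of 12834 genes, 6622 up and 2590 down (4093 up and 4614 down after median-of-ratios scaling, which shifts the median of all genes by -0.44 log2). For the interaction it called 6496 of 12834 genes, 4450 up and 2046 down (2566 up and 2989 down after median-of-ratios scaling, which shifts the median of all genes by -0.25 log2).

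SGC0946, given at 1 uM from day 0, was used to ask which genes depend on DOT1L activity, with 2 libraries in PBS and 3 in each other group. Dot1l (NM_199322, mm10 chromosome 10, 80755203 to 80795461) was at 34.2 ± 1.31 against 42.5 ± 2.06 TPM with inhibitor against vehicle in PBS (adjusted p = 0.13). It was at 156 ± 5.55 against 224 ± 15.4 TPM with MSUc (adjusted p = 0.0013). With MSUc genes of the DOT1L complexes were lower, 0 and 6 of 11 (0 and 7 adjusted over the list alone, fry adjusted p = 0.0016) up and down. Aff1 changed by -0.58 ± 0.07 and Kmt2a by -0.69 ± 0.12. Lysosomal CLEAR genes gave 5 and 15 of 41 (6 and 16 adjusted over the list alone, fry adjusted p = 0.00026), or fry adjusted p = 0.11 with voom on recovered reads. Psap, a precursor of lipid hydrolase activators, stood at 5370 ± 90.9 against 7349 ± 130 TPM and Gpnmb at 7501 ± 129 against 10790 ± 770 TPM. NRF2 targets gave 6 and 0 of 20 (8 and 0 adjusted over the list alone, fry adjusted p = 0.0087) and mitochondrial genes 5 and 1 of 20 (7 and 2 adjusted over the list alone, fry adjusted p = 0.0032), with Cox5a at 0.51 ± 0.08. Of the lipid genes Apoe rose (2501 ± 268 against 1139 ± 55.1 TPM), as did Fabp5 (708 ± 26.1 against 296 ± 43.5 TPM). Lars2, a mitochondrial tRNA ligase gene, fell by 1.55 ± 0.12 (47 ± 3.17 against 139.9 ± 15 TPM). The ribosomal protein gene Rpl36 rose by 3.49 ± 0.28. Short transcripts were higher and long ones lower with SGC0946 and MSUc (Spearman rho = -0.49 with length), which runs through each of these groups. Vehicle MSUc libraries held 2.83 to 6.63 M reads, 0.22 to 0.29% from rRNA genes (SGC0946 8.64 to 12.2 M and 0.09 to 0.10%). Dendritic cell markers were higher with SGC0946 and MSUc, 3 and 0 of 7 (4 and 0 adjusted over the list alone, fry adjusted p = 0.023), or 0.059, 0.053 and 0.076 without SGC0946 MSUc replicate 1, 2 or 3. Neutrophil markers were lower, 0 and 1 of 4 (fry adjusted p = 0.015), or 0.062 from the compared groups alone, 0.053 and 0.1 without SGC0946 MSUc replicate 1 or 3, and on balance up with no filter (0.61). In PBS neutrophil markers were higher, 0 and 0 of 4 (1 and 0 adjusted over the list alone, fry adjusted p = 0.003), and those of dendritic cells gave 1 and 0 of 7 (3 and 0 adjusted over the list alone, fry adjusted p = 0.047), which did not pass from the compared groups alone (0.24), with the replicate block (0.079) or after median-of-ratios scaling (0.052). Nor did the latter without vehicle PBS replicate 1 or 2 or SGC0946 PBS replicate 2 or 3 (0.089, 0.099, 0.2 and 0.098). In PBS the cholesterol synthesis list was lower, 0 and 0 of 18 (fry adjusted p = 0.0061), with fry adjusted p = 0.094 from the compared groups alone.

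For MSUc with vehicle limma called 6832 of 12324 genes, 2188 up and 4644 down (3043 up and 3155 down after median-of-ratios scaling, which shifts the median of all genes by 0.22 log2). For SGC0946 it called 83 of 12324 genes, 54 up and 29 down in PBS and 2050 of 12324 genes, 911 up and 1139 down (1072 up and 911 down after median-of-ratios scaling) with MSUc. For the interaction it called 4 of 12324 genes, 4 up and 0 down. From the compared groups alone 0 genes passed in PBS by limma (1814 at an unadjusted p under 0.05) and 1017 with MSUc. With the replicate block limma called 1 gene in PBS and 0 for the interaction (1218 and 1235 at an unadjusted p under 0.05). With voom on recovered reads the counts were 578 in PBS and 232 for the interaction. Leaving out vehicle PBS replicate 1, 2 or 3 or SGC0946 PBS replicate 2 or 3 gave 5, 37, 20, 0 or 0 genes in PBS by limma (804 and 592 at an unadjusted p under 0.05 for the counts of 0). Leaving out SGC0946 MSUc replicate 1 or 3 gave 1144 or 1129 with MSUc. The interaction count was 8 and 8 without vehicle PBS replicate 1 or 2, 42 or 20 without vehicle MSUc replicate 1 or 2, and 2 without SGC0946 MSUc replicate 2. By limma it was 0 without SGC0946 PBS replicate 2 or 3 or SGC0946 MSUc replicate 1 (708, 869 and 1152 at an unadjusted p under 0.05).

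Metformin, which lowers mitochondrial respiration and activates AMPK, was compared with vehicle in 3 libraries per group, its dose not being stated. In PBS Trib3, a stress response pseudokinase gene, rose to 193 ± 2.54 against 7.91 ± 1.39 TPM. Ddit3, which encodes CHOP, rose to 415 ± 27.3 against 46.7 ± 11.2 TPM and the metallothionein gene Mt2 to 378 ± 53.7 against 29 ± 5.11 TPM. Genes of the integrated stress response gave 15 and 4 of 24 (15 and 5 adjusted over the list alone, fry adjusted p = 3e-06) up and down, with Asns at 1.90 ± 0.08. Cholesterol synthesis genes fell, 1 and 15 of 19 (2 and 15 adjusted over the list alone, fry adjusted p = 4.4e-07). So did macrophage identity genes, 1 and 17 of 20 (fry adjusted p = 2.4e-07), with Csf1r at 275 ± 1.34 against 972 ± 39 TPM. Markers of other cells moved with them, those of neutrophils by 0 and 4 of 7 (0 and 5 adjusted over the list alone, fry adjusted p = 0.0033) and those of dendritic cells by 0 and 3 of 7 (fry adjusted p = 0.0015), and with MSUc 0 and 4 of 7 (0 and 5 adjusted over the list alone, fry adjusted p = 0.022) and 0 and 5 of 7 (0 and 6 adjusted over the list alone, fry adjusted p = 0.00015). For neutrophil markers with MSUc fry adjusted p was 0.097 from the compared groups alone, 0.091 and 0.056 without vehicle MSUc replicate 2 or 3, and 0.081 and 0.067 without metformin MSUc replicate 1 or 3. Mast cell markers rose in PBS, 1 and 0 of 3 (fry adjusted p = 0.0013) (0.097 with no filter). The integrin gene Itgal fell by 3.61 ± 0.10 (4.05 ± 0.191 against 60.8 ± 2.79 TPM). With MSUc Il10 was at 0.571 ± 0.21 against 21.3 ± 2.00 TPM and Cxcl10 at 5.98 ± 2.48 against 39.8 ± 6.26 TPM with metformin against vehicle. Inflammatory genes gave 1 and 12 of 24 (1 and 15 adjusted over the list alone, fry adjusted p = 0.0011) and NF-kappaB feedback genes 2 and 10 of 18 (fry adjusted p = 0.00064), with Nfkbia at -1.16 ± 0.09. Immediate early genes gave 1 and 22 of 30 (1 and 23 adjusted over the list alone, fry adjusted p = 0.0012) and cholesterol synthesis genes 0 and 12 of 19 (fry adjusted p = 5.3e-06). Lysosomal CLEAR genes gave 17 and 7 of 41 (fry adjusted p = 0.00068). Their balance turned from up to down after median-of-ratios scaling (fry adjusted p = 0.83).

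By the interaction Gdf15 went from 251 ± 6.41 to 506 ± 57.7 TPM with MSUc under metformin and from 35.9 ± 2.78 to 456 ± 20.9 TPM under vehicle. These responses differed by -2.63 ± 0.12. Il10 went from 0.145 ± 0.252 to 0.571 ± 0.21 TPM and from 0.408 ± 0.209 to 21.3 ± 2.00 TPM. The responses of NRF2 targets, 0 and 8 of 20 (fry adjusted p = 0.00024) up and down, and of glycolysis genes, 1 and 8 of 23 (1 and 14 adjusted over the list alone, fry adjusted p = 0.00012), were lower with metformin. So was that of stress response genes, 0 and 11 of 24 (0 and 12 adjusted over the list alone, fry adjusted p = 0.00012). Hmox1 differed by -2.10 ± 0.20 and Slc2a1 by -1.32 ± 0.16. The response of macrophage identity genes was higher, 7 and 0 of 20 (8 and 0 adjusted over the list alone, fry adjusted p = 0.00091), with Mertk at 1.33 ± 0.24. Sesn1 differed by 1.94 ± 0.19. For MSUc with vehicle limma called 6739 of 12514 genes, 2451 up and 4288 down (3238 up and 3289 down after median-of-ratios scaling, which shifts the median of all genes by 0.13 log2). For metformin it called 4946 of 12514 genes, 2908 up and 2038 down (2392 up and 2408 down after median-of-ratios scaling) in PBS. With MSUc it called 5450 of 12514 genes, 3700 up and 1750 down (2455 up and 2722 down after median-of-ratios scaling, which shifts the median of all genes by -0.15 log2). For the interaction it called 1532 of 12514 genes, 941 up and 591 down (671 up and 872 down after median-of-ratios scaling), or 999 without metformin PBS replicate 1.

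**Figure D3:**
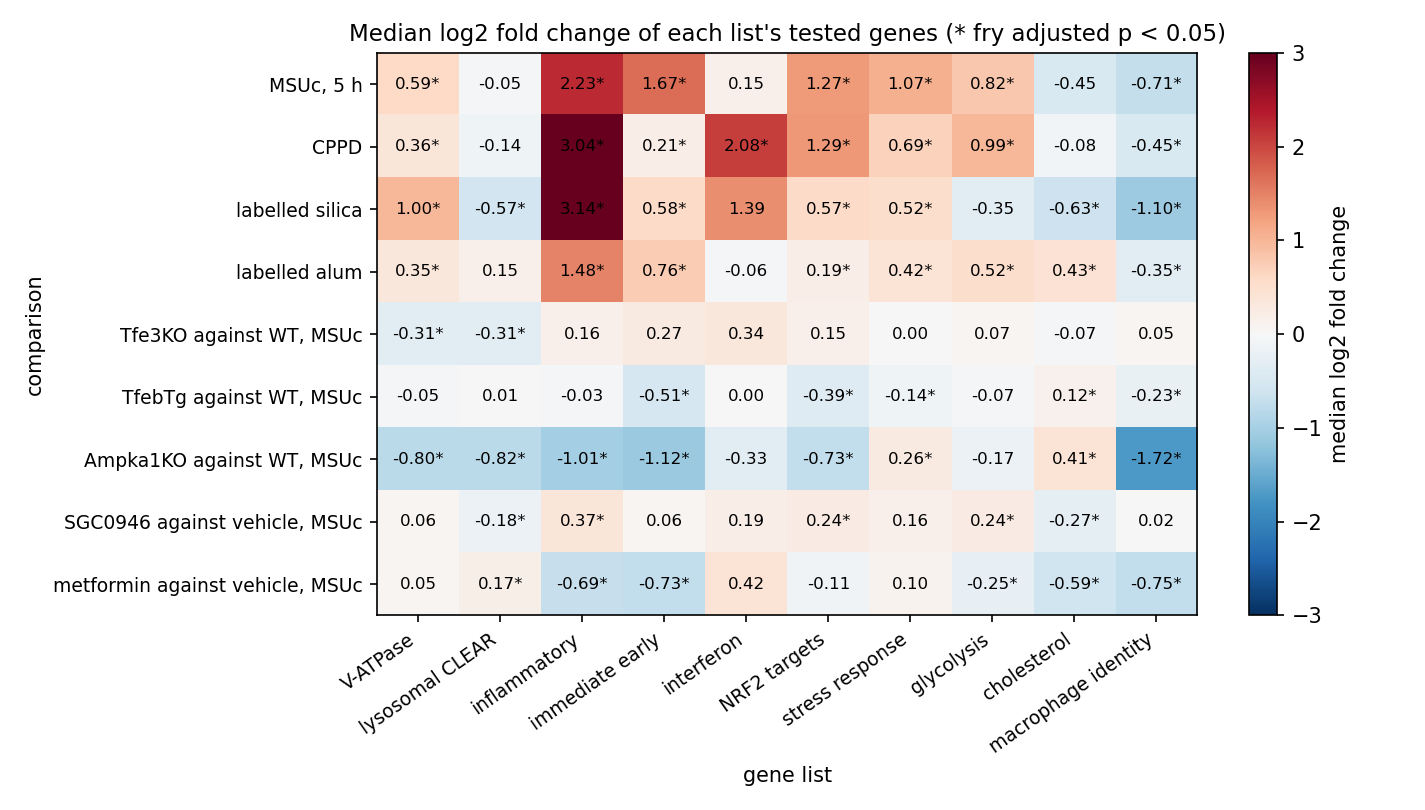
Median log2 fold change of the tested genes of 10 gene lists (columns) in 9 comparisons (rows of the grid), colour and number giving the median and a star marking a fry adjusted p under 0.05. V-ATPase medians run from 1.00 in libraries labelled silica to -0.80 for Ampka1KO against Ampka1WT with MSUc. After median-of-ratios scaling the lysosomal CLEAR balance changed sign with MSUc at 5 hours, with CPPD, for TfebTg and for metformin. Of these only that with CPPD then had a fry adjusted p under 0.05.

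The region lists asked where chromatin changes with MSUc. The authors list 4756 DOT1L, 4446 TFE3 and 5667 TFEB peaks as gained and 4208 DOT1L peaks as reduced, each more than 3 kb from a start site. The labels list 1 MSUc and 2 PBS libraries for TFE3, so its gained peaks rest on 1 MSUc library, with 2 and 3 for TFEB and 3 and 3 for DOT1L. They list 2081 H3K27ac and 1168 H3K4me3 regions as gained and 1838 and 868 as reduced. Of the gained H3K27ac regions 4% lie in promoters, against 28.1% of the reduced ones. Of the former a gained TFEB peak overlapped 1155 (55.5%) and a gained DOT1L peak 926 (44.5%). Of 4446 gained TFE3 peaks 1855 (41.7%) overlapped a TFEB peak. No overlap by chance was estimated. Among lists, 18 of 41 lysosomal CLEAR genes were nearest to a gained TFE3 peak, 18 of 30 immediate early genes to a gained DOT1L peak, and 11 of 21 macrophage identity genes to a region with reduced H3K27ac.

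Genes nearest to gained regions were compared with the 5 hour calls by Fisher's exact test, two-sided, over 12350 genes and 16 tests. Of genes near a gained H3K27ac region 49.3% rose, against 13.8% of the others (odds ratio 6.08, adjusted p = 2.5e-129), and near a gained H3K4me3 region 55% against 14.5% (7.18, 8.7e-104). Near gained DOT1L peaks 38.2% rose against 12.7% (4.26, 1.4e-132), near TFEB peaks 35.3% against 12.2% (3.92, 5.1e-133), and near TFE3 peaks 30.6% against 13.5% (2.81, 3e-71). Near reduced H3K4me3 regions 72.2% fell against 31.5% (5.66, 3.1e-66). Near reduced DOT1L peaks both rises (1.15, 0.034) and falls (1.31, 3.9e-07) were more frequent, and with only start sites within 10 kb the odds ratio for rises was 0.709 (adjusted p = 0.013). Neighbouring genes share regions, so these p values treat as independent what is not entirely so.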

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

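The tests on stromal genes, the scaling test on ribosomal protein genes and the splits that keep same-numbered libraries together were chosen only after the result was seen. The test of transcript length was set before its values were computed, after short genes had been noticed among the largest changes.

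In Ampka1KO libraries stromal genes were higher than in Ampka1WT libraries in PBS and with MSUc, as for Acta2 (1010 ± 135 against 45.4 ± 15.9 TPM in PBS and 2410 ± 116 against 67.2 ± 25 TPM with MSUc, n = 3) and Col1a1 (583 ± 145 against 49.4 ± 18.6 TPM in PBS). All 9 tested genes of the stromal list passed in both media after median-of-ratios scaling, which argues against scaling as the cause. All 9 also lay higher in every Ampka1KO than in every Ampka1WT library in both media, which is consistent with more cells of another type in the Ampka1KO cultures, a candidate explanation since the labels state no sort that would remove them. Of the macrophage list 5 genes rose and 12 fell in PBS, while Lyz2 stood at 20900 ± 1400 against 34500 ± 1810 TPM and Csf1r at 605 ± 71.1 against 1070 ± 127 TPM. An effect of the genotype on these genes within macrophages stays open as untested, and 7 of the 9 genes were above 1 TPM in Ampka1WT libraries too.

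Ribosomal protein genes fell in libraries labelled alum (66 of 84, median log2 change -1.30) and rose with SGC0946 and MSUc (54 of 82, median 0.83). After median-of-ratios scaling the medians were -1.39 and 0.88, which argues against scaling. Other protein-coding transcripts under 1 kb moved the same way. Their median less that of longer genes was -1.03 log2 for alum and 0.56 with SGC0946 and MSUc. Both may be a bias by transcript length, as RNA quality or library preparation may bring. Spearman's rho with length was 0.55 and -0.49 across genes, which are not independent. A loss of short transcripts through the particle itself, or a gain through the inhibitor, stays open as untested.

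The particle columns and the sample labels differ in their numbers of silica and alum, so an exchange of both names was tested. Across 12096 genes the changes in columns named for silica correlated with those of silica in Tfe3WT libraries with r = 0.87, and those in columns named for alum with r = 0.38, a difference of 0.49 that argues against exchanged names. A single wrong name among the columns not used here stays open, and no biological explanation was tested.

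The response to particles differed between genotypes by an interaction test in limma for 221 genes with MSUc, 119 with CPPD and 194 with silica in the Tfe3 experiment. It differed for 12 genes between TfebTg and TfebWT (41 with voom on recovered reads and 6 with the replicate block). It differed for 1 gene between Bhlhe40KO and WT and for 16 between Bhlhe41KO and WT (64 with voom on recovered reads). It differed for 6496 genes between Ampka1KO and Ampka1WT. It differed for 4 genes between SGC0946 and vehicle, or 232 with voom on recovered reads and 0 by limma with the replicate block (1235 at an unadjusted p under 0.05). It differed for 1532 genes between metformin and vehicle.

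For groups of 3 against 3 the 10 splits are too few for a share under 0.05, and the real split was the 1 of 10 with the largest count each time. With MSUc, CPPD and silica against PBS in Tfe3WT the real split gave 7883, 7703 and 8424 genes and the highest other split 0, 0 and 2. MSUc and CPPD in the comparison of particles gave 7757 and 6454 against 1 and 1. Tfe3KO against Tfe3WT gave 303 in PBS against 109, and 1372 with MSUc against 1. TfebTg with MSUc gave 417 against 1. MSUc in Ampka1WT gave 8169 against 2, and Ampka1KO 6117 in PBS and 9212 with MSUc against 1 and 1. MSUc under vehicle gave 6832 against 1 and SGC0946 with MSUc 2050 against 2. In the metformin experiment MSUc under vehicle gave 6739 against 2, and metformin 4946 in PBS and 5450 with MSUc against 2 and 4.

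Of 100 splits of the same libraries drawn from 200, the real split included, as many genes were called in 12 splits for Tfe3 with MSUc (highest other 1392), 7 with CPPD (1124) and 10 with silica (1145), so these splits do not exclude chance. They exchange single libraries, although Xist follows the replicate number through all 4 Tfe3KO groups. With same-numbered libraries exchanged together, the real split gave 221, 119 and 194 genes and the highest other split 2, 1 and 2, but 10 splits are too few for a share under 0.05. The share was under 0.05 for Ampka1 (2 of 100, highest other 6666) and metformin (2 of 100, highest other 2206). The highest of the other splits exchanged 6 PBS libraries between genotypes for Tfe3 with MSUc and CPPD, 2 with silica, 4 for Ampka1 and 6 for metformin, and 0, 0, 0, 0 and 2 libraries with the particle. Exchanging PBS libraries turns a difference between genotypes or drugs that holds in both media into an interaction, so these large counts point to that structure of the samples.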

How the results depend on the processing

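Median-of-ratios scaling, voom on recovered reads, the crossed numbers, the removal of all 4 Tfe3KO libraries numbered 1 and the refits behind the region tests were chosen only after the data were seen. Each other choice was changed alone.

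For MSUc in the 8 experiments (5 hours if timed) and other particles every setting run left total calls within 1.5 times of those reported. So it did for Ampka1KO and metformin in PBS or MSUc, but not for TfebWT with replicate 3 regrouped. A minimum change was set only for shared genes and overlaps. Median-of-ratios scaling moved rises or falls more (3948 to 1975 falls in TfebWT). Among comparisons of named genes with another setting, libraries left out aside, 878 kept direction and side of the threshold, 26 lost the call and 3 turned. Of those of lists 641 kept both, 27 lost the call, 2 gained it and 8 turned. Of all 468 list calls 317 held in 6 settings, 67 were lost under median-of-ratios scaling and 82 with some library left out. Direction turned for 20 of the 468 in some setting, 17 of them under median-of-ratios scaling.

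With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, limma called 0 genes after 10 and 30 minutes, 56 after 1 hour and 1015 after 2 hours. It called 0 for Tfe3KO in PBS and 767 with MSUc, and 78, 37 and 9 for its interactions with MSUc, CPPD and silica. It called 33 for TfebTg in PBS and 189 with MSUc. For Bhlhe40KO and for Bhlhe41KO it called 0 in PBS and 0 with MSUc, and 2 and 5 for their interactions, and 0 for SGC0946 in PBS and 1017 with MSUc. The counts at an unadjusted p under 0.05 stand in the report.

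With no filter, where more genes are tested, Bhlhe40KO gave 6 genes in PBS, 4 with MSUc and 5 for the interaction, Bhlhe41KO 167 in PBS and 9 for the interaction, and SGC0946 13 for the interaction. With a pseudocount of 0.1 the 10 minute count was 2. Under median-of-ratios scaling the Bhlhe41KO interaction count was 4. With voom on recovered reads the 10 minute count was 2, and TfebTg gave 243, 654 and 41 genes in PBS, with MSUc and for the interaction. Bhlhe40KO gave 3 in PBS and 0 for the interaction (527 at an unadjusted p under 0.05), Bhlhe41KO 714, 354 and 64, and SGC0946 578 in PBS and 232 for the interaction. The cause was not tested for these.

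By correlation same-numbered libraries were paired in 1 of the contrasts with 3 pairs, and 2 pairs were taken as too few to tell. Xist and Ddx3y follow the number across treatments in Tfe3KO and in the WT and Bhlhe40KO libraries of the Bhlhe experiment, so numbers may mark donors there. The replicate block gave 286, 154 and 291 genes for the Tfe3 interactions with MSUc, CPPD and silica. It gave 6 genes for the Tfeb interaction, 0 for that of Bhlhe40KO (649 at an unadjusted p under 0.05), 1 for SGC0946 in PBS and 0 for its interaction, and changed no other count by over 1.5 times and no other named call except those of the cell cycle list with MSUc in Tfe3WT (fry adjusted p = 0.0055) and of dendritic cell markers with SGC0946 in PBS (0.079). Every library correlated best with its own number in 6 contrasts of 3 pairs, MSUc and CPPD among the 4 particles, CPPD and silica in Tfe3WT, and MSUc with vehicle and metformin in PBS, a hint from the data only. With numbers crossed between PBS and MSUc the counts after 10 minutes, 30 minutes and 1 hour were 15, 144 and 1078.

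With TfebWT MSUc replicate 3 grouped with PBS, the Tfeb counts were 1, 8, 36 and 3 and 0 genes passed in all 8 by limma, a library like MSUc then widening the spread of PBS. Without the 4 Tfe3KO libraries numbered 1, Tfe3KO in PBS gave 463 genes and the silica interaction 637. With an absolute log2 change of at least 1, which passes fewer genes by construction, 581 genes were shared by all 8 experiments. Overlaps were then 1145 for MSUc and CPPD, 1122 for MSUc and silica, 741 for MSUc and alum, 914 for CPPD and silica, 544 for CPPD and alum and 467 for alum and silica. In Tfe3WT they were 1065, 1018 and 887 for MSUc and CPPD, MSUc and silica, and CPPD and silica.

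Near reduced DOT1L peaks the odds ratio for rises was 1.12 with the compared groups alone, 1.11 under median-of-ratios scaling and 1.14 with the replicate block, no longer past the threshold, and turned to 0.709 with start sites within 10 kb. Near gained TFE3 peaks that for falls was 0.922 with no filter and no longer passed. Under median-of-ratios scaling Prkaa1 in Ampka1KO turned to -0.11 in PBS and -0.13 with MSUc, and with voom to -0.03 in PBS. The balance of lysosomal CLEAR genes turned under median-of-ratios scaling at 5 hours (fry adjusted p = 0.59), for TfebTg with MSUc (0.95) and for metformin with MSUc (0.83), a change of direction that this scaling brings by adding the same amount to every gene of a library. The list turned from down to up past the threshold with MSUc under vehicle in the SGC0946 experiment (from 0.00051 to 0.0011), in TfebWT (0.092 to 0.0035), in Tfe3WT (0.57 to 6e-05) and among the particles (0.64 to 0.00029), and with CPPD in Tfe3WT (0.023 to 0.00054) and among the particles (0.34 to 0.014). Under this scaling the balance of interferon-stimulated genes with MSUc turned to up in TfebWT (0.75), Tfe3WT (0.69) and the Bhlhe experiment (0.58, and 0.58 from the compared groups alone). That of neutrophil markers with SGC0946 and MSUc turned with no filter (0.61).

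With each library left out in turn (a lone library being assumed to vary like the other groups), the ranges were 2 to 10 genes after 10 minutes, 46 to 100 after 30 minutes, 192 to 250 after 1 hour and 2701 to 3315 after 2 hours. They were 143 to 487 for Tfe3KO in PBS, and 128 to 422, 67 to 327 and 52 to 729 for its interactions with MSUc, CPPD and silica. For TfebTg they were 30 to 59 in PBS, 214 to 391 with MSUc and 4 to 12 for the interaction. For Bhlhe40KO they were 1 to 5, 2 to 4 and 0 to 4 (552 to 769 at an unadjusted p under 0.05 where limma called 0), and for Bhlhe41KO 41 to 114, 6 to 193 and 1 to 18. For SGC0946 they were 0 to 37 (592 and 804 at an unadjusted p under 0.05 for the counts of 0), 1129 to 2179 and 0 to 42, and 999 to 1946 for the metformin interaction. The odds ratio for rises near reduced DOT1L peaks ranged from 1.15 to 1.22. The libraries that moved a count by over 1.5 times are named beside it in the report.

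Depth limits genes near the filter most, since at 2.12 M reads, the lowest total, a gene at 1 TPM holds few reads. The planned count-based alternatives were not run because the tables hold TPM, nor stricter peak lists for DOT1L, TFE3 and TFEB, whose scores are all 0, nor a split of the PBS controls, too few to leave 2 in each part.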

Other observations

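The tests of peaks against genes, and Ifi202b, were chosen only after the result was seen.

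After 5 hours of MSUc, with 2 libraries per group, the folliculin partner genes Fnip1 (80.8 ± 1.02 against 36.1 ± 3.69 TPM) and Fnip2 (275 ± 34.9 against 71.4 ± 11.6 TPM) rose. Of the bHLH factors that bind E-boxes, Usf1 fell by 1.53 ± 0.13 (14.7 ± 1.4 against 44.3 ± 0.96 TPM). Up and down, heat shock genes gave 6 and 0 of 10 (fry adjusted p = 2.2e-05). Genes of osteoclasts and cell fusion gave 3 and 1 of 8 (fry adjusted p = 2.2e-05), among them the integrin gene Itgb3 (4.85 ± 0.0304 against 0.823 ± 0.315 TPM). Among autophagy genes the cargo receptor gene Sqstm1 rose by 2.38 ± 0.16 and Vps18 by 1.35 ± 0.08. Ulk2, an autophagy kinase gene, fell by 1.79 ± 0.12 and Wipi1 by 1.51 ± 0.10.

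Interferon-stimulated genes fell with MSUc in Ampka1WT libraries, 5 and 13 of 23 (fry adjusted p = 5.8e-06) up and down (n = 3), though Isg15 and Rsad2 rose there as in all 8 experiments. With MSUc they gave 3 and 9 of 27 (fry adjusted p = 0.017) in TfebWT (0.059 from the compared groups alone, 0.75 and up after median-of-ratios scaling, 0.12 without TfebWT PBS replicate 1). They gave 3 and 9 of 25 (3 and 8 adjusted over the list alone, fry adjusted p = 0.078) and 5 and 7 of 25 (fry adjusted p = 0.61) under vehicle in the drug experiments and 3 and 5 of 27 (2 and 2 adjusted over the list alone, fry adjusted p = 0.8) in Tfe3WT. They gave 4 and 4 of 27 (3 and 4 adjusted over the list alone, fry adjusted p = 0.89) in the Bhlhe experiment and 4 and 0 of 27 (fry adjusted p = 0.54) at 5 hours, and the particle comparison stands in the report. Cell cycle genes fell in Ampka1WT too, 4 and 15 of 23 (4 and 17 adjusted over the list alone, fry adjusted p = 0.0012), with the cyclin gene Ccna2 at 26.4 ± 2.87 against 80.2 ± 9.12 TPM. They also fell with MSUc in TfebWT, 2 and 13 of 23 (2 and 14 adjusted over the list alone, fry adjusted p = 2.1e-05), and under vehicle in the SGC0946 experiment, 1 and 11 of 23 (fry adjusted p = 1.9e-05), where the cell cycle inhibitor gene Cdkn1a rose (389 ± 43.9 against 106 ± 16.6 TPM). In other MSUc comparisons they gave 2 and 16 of 23 (fry adjusted p = 0.0028) among the particles (0.079 after median-of-ratios scaling and 0.05 from the compared groups alone) and 2 and 8 of 23 (fry adjusted p = 0.06) in Tfe3WT (0.0055 with the replicate block and 0.034 with voom on recovered reads). They gave 3 and 4 of 23 (3 and 2 adjusted over the list alone, fry adjusted p = 0.65) under vehicle in the metformin experiment, 2 and 2 of 23 (fry adjusted p = 0.7) in the Bhlhe experiment and 1 and 2 of 23 (0 and 1 adjusted over the list alone, fry adjusted p = 0.61) at 5 hours. Stromal markers rose with MSUc under vehicle in the SGC0946 experiment, 7 and 0 of 8 (fry adjusted p = 0.004), and in TfebWT, 2 and 0 of 6 (fry adjusted p = 0.0097) (0.086 from the compared groups alone and 0.079 without TfebWT PBS replicate 1). With silica in Tfe3WT the neutrophil marker S100a8 was at 579 ± 29 against 119 ± 46.2 TPM. The neutrophil list gave 10 and 1 of 13 (11 and 1 adjusted over the list alone, fry adjusted p = 0.00012) up and down and the mast cell list 5 and 0 of 5 (fry adjusted p = 2.6e-07). Tfeb itself fell with silica in Tfe3WT (19.5 ± 1.45 against 52.1 ± 3.5 TPM).

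A hypothesis was that gained DOT1L peaks may mark genes that depend on DOT1L activity. Among 2188 genes raised by MSUc under vehicle, 23.1% of those nearest to a gained DOT1L peak fell with SGC0946, against 16.3% of the others (odds ratio 1.54, interval 1.23 to 1.94, adjusted p = 0.00042, Fisher's exact test, two-sided, over 9 tests). The same test with TFE3 or TFEB peaks gave odds ratios of 1.62 and 1.59 (adjusted p = 0.00019 for each), so the relation is not particular to DOT1L peaks. It also runs with the trend in transcript length, which was not removed. Over all 12324 genes tested the odds ratio for DOT1L peaks was 2.58 for falls and 1.04 for rises with SGC0946.

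Gained TFE3 peaks might likewise mark genes that need TFE3. Among 2564 genes raised by MSUc in Tfe3WT, 15.3% of those near a gained TFE3 peak were lower in Tfe3KO, against 16.5% of the others (odds ratio 0.912, interval 0.712 to 1.16, adjusted p = 0.47). Over all 12796 genes the odds ratio was 1.65 for falls (adjusted p = 1.2e-08) and 2.47 for rises (3.3e-18), so the peaks go with change in either direction, and whether they mark a need for TFE3 stays open. For gained TFEB peaks and genes higher in TfebTg with MSUc, among 1507 raised genes, the shares were 5.6% and 3.6% (1.58, interval 0.941 to 2.68, adjusted p = 0.11), and with TFE3 or DOT1L peaks in place of TFEB peaks the odds ratios were 1.93 and 1.9 (adjusted p = 0.019 for each). Over all 11991 genes TFEB peaks gave 4.14 for rises (5e-25) and 3.34 for falls (3.2e-13). The tests among raised genes are Fisher's exact tests, two-sided, from the family of 9, and those over all genes from a family of 6.

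Ifi202b, an interferon-inducible gene, was listed at 0 TPM in the 3 Ampka1WT PBS libraries and at 47.7 ± 7.66 TPM in Ampka1KO.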
